A study of Homo sapiens with 4 samples.

How the data were processed

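The series is native chromatin immunoprecipitation followed by sequencing (ChIP-seq) of H3K9me2 and H3K9me3, the dimethylated and trimethylated forms of lysine 9 of histone H3 that mark heterochromatin. The cells were HCT116, an established human colorectal carcinoma line. Per the labels' protocols, cells received PBS or 300 nM 5-aza-CdR (5-aza-2'-deoxycytidine, also called decitabine, a cytosine analogue that traps DNA methyltransferases and lowers DNA methylation) for 24 h and were harvested at 5 days. Nuclei were prepared as single nucleosomes without cross-linking. Each mark had 1 PBS library and 1 5-aza-CdR library, so the 4 groups held 1 library each and no replicate.

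The deposited table lists 373 subfamilies of long terminal repeats (LTRs), the flanking regulatory repeats of endogenous retroviruses, under their repeat annotation names. It gives a CpG density per subfamily and, per the file headers, a z-score per subfamily for each of the 4 libraries of H3K9me2 and H3K9me3. These deposited values are the authors' standardised score (z-score) and not counts or coverage. The z-score columns are named by mark and treatment, and these names match the sample descriptions. The submitters' processing notes name Bowtie2 and the hg19 genome build. The handling of reads that map to several repeat copies, the use of an input library, and the population over which the z-score was centred and scaled are not given in the sources used here. The z-scores are not centred on the listed subfamilies: no library has mean 0 and SD 1 over them. The deposited CpG density is a ratio whose denominator the header does not state, with values from 0.00171 to 0.0671. No read counts, copy numbers or genomic positions come with these values, so the depth behind each z-score is unknown and no counting interval was computed.

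For each mark the z-score of the PBS library was subtracted from that of the 5-aza-CdR library. With 1 library per group no test of the treatment was possible and no p-value was computed. A limit of size was used in its place: a difference counted as above or below the limit when it lay more than 2 robust SDs (scaled median absolute deviations) from the median difference of all 373 subfamilies. A normal distribution would place 8.49 of 373 subfamilies beyond such a limit on each side. Spearman and Pearson correlations were taken across subfamilies, which are related by descent and are not independent replicates. Their intervals are 95% percentile intervals from 2000 bootstrap draws of the subfamilies and describe these libraries only. Correlations with CpG density were set beside the range of 10000 shuffles of the densities.

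The design had foreseen an evolutionary age per subfamily. The table is named for evolutionary age and has no column of ages, so its CpG density was used in that place, a choice made after seeing the data. Subfamilies were split by CpG density into a high-CpG group of 125, an intermediate group of 124 and a low-CpG group of 124.

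Repeat family lists were fixed by name before the data were examined. Of 19 lists, 9 had at least 3 members in the table and took in 180 subfamilies. The other 10 lists (internal parts of retroviruses, LINE, SINE and SVA elements, DNA transposons and satellites) had no members and were not analysed here. A list's median difference was given as a percentile among 10000 random lists of the same size, matched in 10 equal bins on the mean of the PBS and 5-aza-CdR z-scores, and also as a percentile among unmatched random lists. List levels were set against unmatched random lists. Percentiles below 2.5 or above 97.5 were taken as standing apart.

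Subfamilies were named by a rule fixed before the data were examined: the 6 highest and 6 lowest differences per mark, the 4 highest and 4 lowest z-scores per PBS library, the 3 highest and 3 lowest values of H3K9me3 minus H3K9me2 in PBS, and per list up to 3 members (the highest, the lowest and the nearest to the median). Any other subfamily named is said to have been chosen after its values were seen.

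Alternatives of scale, fixed before the data were examined, were z-scores set again to mean 0 and SD 1 in each library, percentile ranks and residuals. A residual is the signed distance of a subfamily from the principal line through the PBS and 5-aza-CdR values. For H3K9me3, with SD 0.0354 in PBS and 0.206 in 5-aza-CdR, that line runs nearly along the 5-aza-CdR axis. The H3K9me3 residual therefore follows mainly the PBS z-score with its sign turned and is a poor measure of the treatment difference. Also fixed before were a filter that left out the 20% of subfamilies nearest 0, limits of 3 robust SDs or 2 ordinary SDs, and unmatched lists. So were 5 groups in place of 3, foreseen for age and applied here to CpG density. A restriction to LTRs was also foreseen and not run, because the table holds LTR subfamilies only. Alternatives added after seeing the data left out LTR5 and LTR11, the 37 subfamilies with the highest CpG density, or 4 subfamilies whose CpG density is an exact simple fraction, and took the overlap of the marks on the other scales and within the CpG groups.

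The procedures were tested on simulated data first. Of 40 subfamilies shifted by 5 robust SDs among 373, 100% were recovered for H3K9me2 and 100% for H3K9me3. At 3 robust SDs the shares were 57.5% and 72.5%, and at 1 robust SD they were 10% and 12.5%. Of the unshifted subfamilies, 6.91% and 5.11% lay beyond the limit at 5 robust SDs, 0% and 3% at 3, and 3.9% and 2.7% at 1. The simulated differences were normal, with the robust SD of the data and no CpG trend, so these shares need not hold for the data. Of 100 simulated lists of 8 members with no shift, 7 lay outside the central range, against 92 of 100 lists shifted by 1.5 SD. The simulated lists were matched on the H3K9me2 PBS z-score, which the shift did not enter. The lists of the data were matched on a mean that includes the 5-aza-CdR z-score, so this recovery does not carry over to them. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.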

Results

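H3K9me2 and H3K9me3 were profiled by native ChIP-seq in HCT116 colorectal carcinoma cells 5 days after 24 h of PBS or 300 nM 5-aza-CdR, and the values were summarised over 373 LTR subfamilies. Each mark and treatment was represented by 1 library, so none of the differences between treatments has a replicate check. Values are the authors' z-scores, a relative scale, and the sequencing depth behind them is unknown. In the PBS libraries the z-score averaged -0.42 for H3K9me2 (SD 0.187 over the 373 subfamilies) and -0.51 for H3K9me3 (SD 0.0354). In the 5-aza-CdR libraries it averaged 0.27 for H3K9me2 (SD 0.290) and 0.45 for H3K9me3 (SD 0.206). The spread over subfamilies was thus 1.55 times as wide in the 5-aza-CdR library as in the PBS library for H3K9me2 and 5.81 times as wide for H3K9me3.

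The first question was where the 2 marks lay among LTRs in PBS-treated cells. CpG-poor LTRs had the higher z-scores and CpG-rich LTRs the lower ones, for both marks. The handling of reads that map to several copies and the use of an input are not given. Whether z-score levels follow the marks alone was therefore not tested, here and for the families below. For H3K9me2 the highest values were those of LTR11 (0.13), LTR81AB (-0.02), LTR90B (-0.03) and LTR16D1 (-0.03). The lowest were those of the 3 LTRs of HERV-Fc1, a low-copy gammaretrovirus-like family, at -1.15 for HERV-Fc1_LTR2, -0.996 for HERV-Fc1_LTR1 and -0.96 for HERV-Fc1_LTR3, and of MER57E3 at -0.94. The same 4 subfamilies were lowest for H3K9me3, with z-scores of -0.63 for HERV-Fc1_LTR2, -0.62 for MER57E3, -0.61 for HERV-Fc1_LTR3 and -0.61 for HERV-Fc1_LTR1. The highest H3K9me3 values were -0.3 for both LTR11 and LTR5, -0.36 for HERV1_LTRb and -0.39 for LTR90A.

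By retroviral family, the LTR12 repeats of ERV9 had a median H3K9me2 z-score of -0.68 over 7 subfamilies in PBS, at percentile 0.07 of random lists, and a median H3K9me3 z-score of -0.54, at percentile 0.33. The LTR7 repeats of HERV-H (4 subfamilies) had medians of -0.63 for H3K9me2 and -0.54 for H3K9me3, at percentiles 1.91 and 1.41. The LTR5 repeats of HERV-K, which flank the youngest human proviruses, had medians of -0.62 and -0.54 over 4 subfamilies, at percentiles 2.34 and 1.49, and without LTR5 and LTR11 at 3.87 and 2.085. LTR5 itself was at the other end, with z-scores of -0.11 for H3K9me2 and -0.3 for H3K9me3. The 20 subfamilies of the LTR2, LTR8, LTR10, LTR13, LTR17 and LTR22 list had medians of -0.61 and -0.53, at percentiles 0 and 0.16. The old mammalian families were at the other end for H3K9me2: the median was -0.31 over 28 MLT1 subfamilies (percentile 98.7) and -0.29 over 12 MLT2 subfamilies (percentile 97.75, and 97.49 without the 4 subfamilies whose CpG density is a simple fraction). For H3K9me3 the MLT1 and MLT2 medians were -0.50 and -0.49, at percentiles 94.84 and 97.17, which did not stand apart from random lists. The primate MaLR families THE1 (4 subfamilies) and MST (6 subfamilies) did not stand apart for either mark, with H3K9me2 medians of -0.40 and -0.41 and H3K9me3 medians of -0.49 and -0.50. The 95 subfamilies of the MER list had medians of -0.45 and -0.51, at percentiles 5.715 and 5.025.

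The 2 marks ordered the LTR subfamilies alike in PBS, with a Spearman correlation of 0.76 (95% bootstrap interval 0.70 to 0.82) and a Pearson r of 0.73 across subfamilies. With CpG density held constant the partial Spearman correlation was 0.58. In the 5-aza-CdR libraries the Spearman correlation between the marks was 0.85 (0.80 to 0.88). The z-score difference H3K9me3 minus H3K9me2 in PBS had a median of -0.09, with 13 subfamilies above and 4 below the limit of 2 robust SDs. It was highest at HERV-Fc1_LTR2 (0.52), HERV1_LTRb (0.48) and HERV-Fc1_LTR1 (0.39) and lowest at LTR16D1 (-0.46), LTR11 (-0.43) and LTR81AB (-0.42). The spread of H3K9me2 was much the wider, so these differences follow mainly the H3K9me2 value: on the scale with SD 1 in each library, 18 subfamilies lay above the limit, of which 3 were shared with the 13, and LTR11 moved from the lowest side to the highest.

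The table orders LTRs by CpG density, which falls with time in methylated repeats as methylated cytosines mutate, and the second question was how each mark followed it. The H3K9me2 z-score in PBS had a median of -0.57 in the high-CpG group (interquartile range -0.67 to -0.49, 125 subfamilies), -0.41 in the intermediate group and -0.27 in the low-CpG group (-0.35 to -0.20, 124 subfamilies). The corresponding H3K9me2 medians in the 5-aza-CdR library were -0.0069, 0.31 and 0.48. The H3K9me3 medians were -0.53, -0.50 and -0.49 in PBS and 0.30, 0.48 and 0.56 in 5-aza-CdR. Across the 373 subfamilies, the Spearman correlation between z-score and CpG density was -0.74 (-0.79 to -0.68) for H3K9me2 in PBS, -0.77 (-0.81 to -0.72) for H3K9me2 in 5-aza-CdR, -0.61 (-0.68 to -0.53) for H3K9me3 in PBS and -0.67 (-0.73 to -0.60) for H3K9me3 in 5-aza-CdR. The corresponding Pearson r values were -0.62, -0.68, -0.50 and -0.54. Over 10000 shuffles of the densities, the Spearman correlation stayed between -0.21 and 0.24 in these 4 libraries. The trend was present in all 4 libraries, and effects of read mapping or of a missing input on it could not be separated from the marks.

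**Figure D1:**
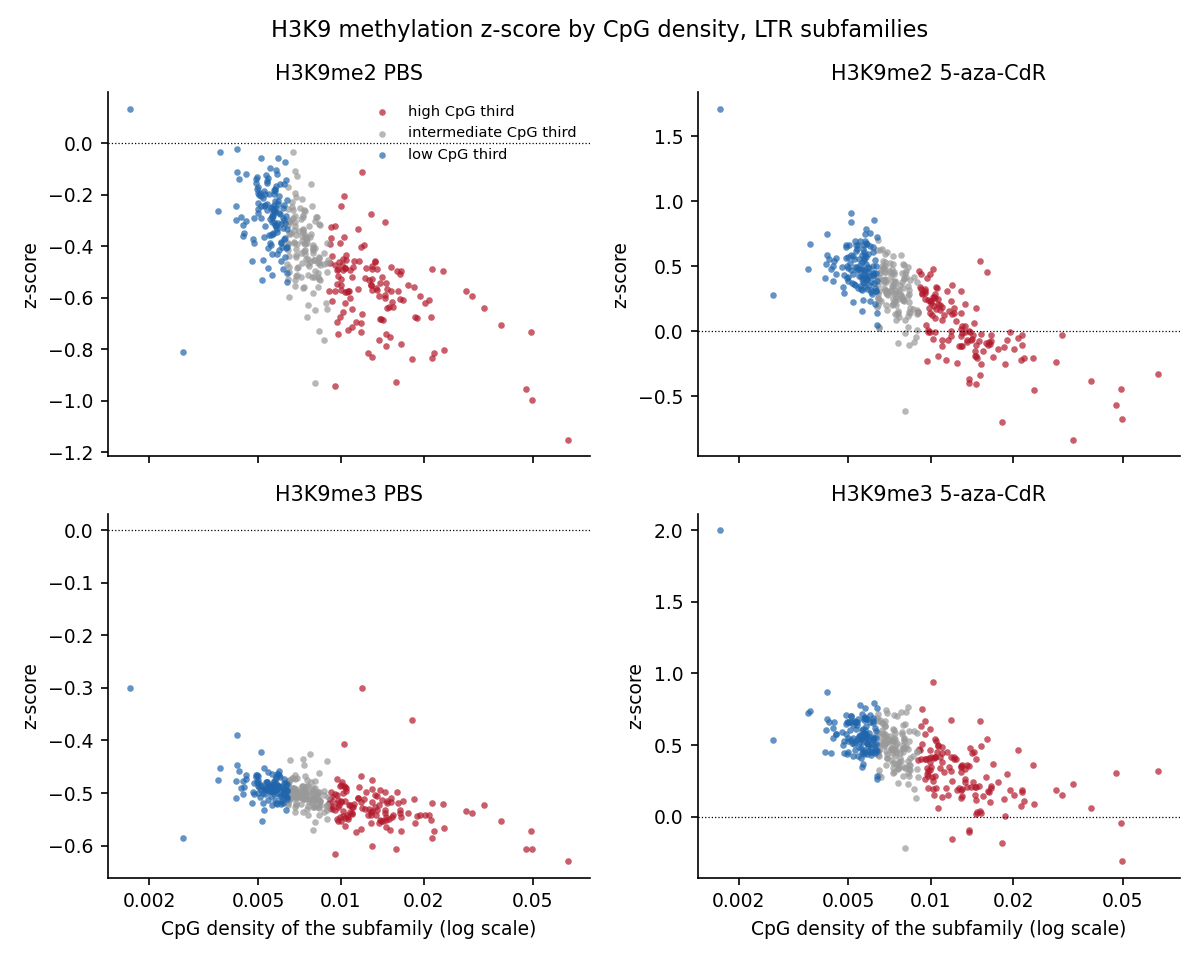
The z-score (y axis, authors' scale) of each of the 373 LTR subfamilies is plotted against its CpG density (x axis, log scale) in 4 panels, 1 per library, with points coloured by CpG group and a dotted line at 0. The z-score was lower at higher CpG density in each library, with Spearman correlation from -0.77 to -0.61, and the H3K9me3 PBS panel spans the narrowest range (SD 0.0354).

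The main comparison was 5-aza-CdR against PBS for H3K9me2. The z-score was higher in the 5-aza-CdR library at 372 of 373 subfamilies, with a median difference of 0.70 (interquartile range 0.61 to 0.78). HERV-Fc2_LTR was the exception, with z-scores of -0.64 in PBS and -0.84 in 5-aza-CdR, a difference of -0.20. Relative to the median difference, 11 subfamilies lay above and 30 below the limit of 2 robust SDs (0.25). The largest differences were those of LTR11 (1.58), MER57E3 (1.27), LTR70 (1.09), LTR89 (1.08), LTR3B_ (1.02) and MamRep1527 (1.005). After HERV-Fc2_LTR, the smallest were those of HERV1_LTRb (0.14), LTR21B (0.23), LTR2C (0.29), LTR12E (0.29) and HERV-Fc1_LTR1 (0.32). Of the 30 subfamilies below the limit, 29 were in the high-CpG group.

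For H3K9me3 the z-score was higher in the 5-aza-CdR library at 373 of 373 subfamilies, with a median difference of 0.97 (interquartile range 0.87 to 1.06). The 7 subfamilies above the limit of 2 robust SDs (0.29) included LTR11 (2.3), LTR10B1 (1.44), LTR81AB (1.32), MER66D (1.29), MLT1M (1.27) and LTR86A1 (1.26). The 27 below it included LTR5 (0.15), HERV1_LTRb (0.18), HERV-Fc1_LTR1 (0.30), LTR25 (0.34), LTR21B (0.43) and LTR22 (0.45), and 25 of the 27 were in the high-CpG group. The deposited H3K9me3 values of LTR11 in both libraries and of LTR5 in PBS are round numbers, unlike the other values in the table. The H3K9me3 z-score varied so little in PBS that the difference was nearly the 5-aza-CdR value itself, with a Spearman correlation of 0.99 between them, against 0.73 for H3K9me2.

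**Figure D2:**
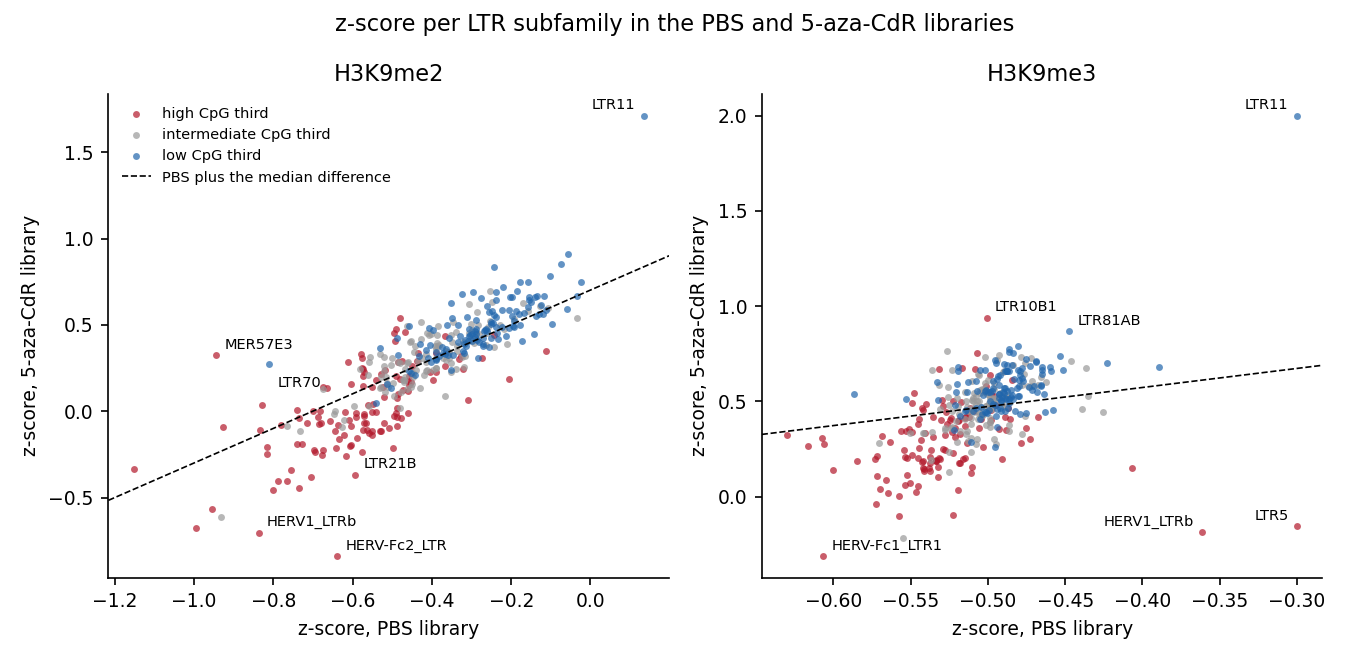
The z-score in the 5-aza-CdR library (y axis) is plotted against that in the PBS library (x axis) for each of the 373 LTR subfamilies, H3K9me2 on the left and H3K9me3 on the right, with points coloured by CpG group and the 3 largest and 3 smallest differences per mark labelled. The dashed line is the PBS z-score plus the median difference (0.70 for H3K9me2, 0.97 for H3K9me3), and the points far below it are mostly in the high-CpG group.

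The limits apply to both marks. What the z-scores were centred and scaled on is not given in the sources used here, so a difference of the whole set between 2 libraries is a difference on the authors' scale and not a measured gain of histone methylation. With mean 0 and SD 1 in each library, which by construction removes the difference in mean and so says nothing about it, the subfamilies beyond the limit numbered 30 above and 11 below for H3K9me2 (11 above and 30 below as deposited) and 20 above and 17 below for H3K9me3 (7 and 27 as deposited). Some named subfamilies lay on the other side as residuals from the principal line, in robust SDs from the median. For H3K9me3, LTR11 (-3.64) and LTR81AB (-1.19) lay below the median, and HERV-Fc1_LTR1 (1.63) and LTR22 (0.0057) above it. These H3K9me3 residuals follow mainly the PBS z-score with its sign turned, so they do not show a treatment difference of the other direction. For H3K9me2, HERV-Fc1_LTR1 (0.26) lay above the median. On ranks, where values at the ends can move little, most of the named subfamilies lay within the limit. For H3K9me2 these were HERV-Fc2_LTR (-0.85), HERV1_LTRb (0), LTR21B (-0.97), LTR12E (-0.22), HERV-Fc1_LTR1 (0.13), LTR11 (0.11) and LTR89 (1.39). For H3K9me3 only LTR10B1, MER66D, LTR5 and HERV1_LTRb stayed beyond it. With SD 1, the H3K9me2 difference of LTR11 (4.85 robust SDs from the median) came behind those of MER57E3 (7.21) and LTR70 (5.10).

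By family, the LTR12 and LTR7 repeats had smaller H3K9me2 differences than the median of all subfamilies, on the deposited scale and on each of the 3 other scales tried. So did the THE1 and MST repeats, by less than LTR12 and LTR7 on the deposited scale. The 7 LTR12 subfamilies had a median H3K9me2 difference of 0.39, with 5 below the limit and 2 within it, from 0.29 at LTR12E through 0.39 at LTR12B to 0.61 at LTR12F. The 4 LTR7 subfamilies had a median of 0.43, with 3 below the limit, from 0.36 at LTR7 to 0.53 at LTR7C. For H3K9me3 the LTR12 median was 0.72, with 3 of 7 below the limit, from 0.53 at LTR12E to 1.01 at LTR12_. The LTR7 median for H3K9me3 was 0.62, with 4 of 4 below the limit, from 0.56 at LTR7Y to 0.67 at LTR7B. The H3K9me3 medians of LTR12 and LTR7 were also below that of all subfamilies, except on the scale of residuals from the principal line, where both were above it. For H3K9me3 the residuals of these lists and of those below follow mainly the PBS z-score with its sign turned. The LTR5 repeats had medians of 0.54 for H3K9me2, with 0 of 4 beyond the limit, and 0.74 for H3K9me3, with LTR5 alone below it. The LTR5 medians lay below those of all subfamilies as deposited, and above them on the residual scale for both marks and on ranks for H3K9me2. LTR5_Hs, the LTR of the human-specific HERV-K proviruses and the member nearest the H3K9me2 median, had a difference of 0.52 for H3K9me2, and LTR5A, nearest for H3K9me3, had 0.77 for that mark.

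The list of LTR2, LTR8, LTR10, LTR13, LTR17 and LTR22 had medians of 0.58 for H3K9me2, with 5 of 20 below and 1 above the limit, and 0.82 for H3K9me3, with 7 of 20 below and 1 above. LTR10B1 was its highest member for both marks (0.97 and 1.44). Its lowest were LTR2C for H3K9me2 (0.29) and LTR22 for H3K9me3 (0.45). Its H3K9me2 median lay below that of all subfamilies as deposited and above it on the other 3 scales, and its H3K9me3 median lay below on the deposited and SD 1 scales and above on ranks and residuals. The MLT1 subfamilies had medians of 0.77 and 1.04, with 28 of 28 within the limit for H3K9me2 and 1 of 28, MLT1M, above it for H3K9me3. The MLT2 subfamilies had medians of 0.74 and 1.04, and 12 of 12 were within the limit for each mark, from 0.59 at MLT2A1 to 0.87 at MLT2B5 for H3K9me2. The MLT1 medians were above those of all subfamilies as deposited, on the SD 1 scale and on ranks, and the H3K9me3 median was below on the residual scale. The MLT2 medians were above as deposited and below on the other 3 scales. The THE1 medians were 0.65 and 0.98 and the MST medians 0.67 and 0.95, with 0 members beyond the limit. For H3K9me2 both lay below the median of all subfamilies as deposited and on the other 3 scales. On ranks THE1 (-0.74 SDs) and MST (-0.55) lay further below it than LTR12 (-0.18) and LTR7 (-0.42). For H3K9me3 the MST median also lay below on each scale, and the THE1 median lay above as deposited and below on the other 3. The MER list had medians of 0.69 and 0.95, with 4 above and 3 below the limit for H3K9me2 and 1 above and 0 below for H3K9me3. Its highest members were MER57E3 for H3K9me2 (1.27) and MER66D for H3K9me3 (1.29).

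Against unmatched random lists, the H3K9me2 difference was at percentile 0 for LTR12, 0.2 for LTR7, 0.07 for the LTR2 to LTR22 list and 99.47 for MLT1. The H3K9me3 difference was at percentiles 0.14, 0.05, 0.1 and 96.97 for the same lists and at 1.22 for LTR5. Against random lists matched on the mean z-score, 0 of 9 lists stood apart for either mark, the nearest being LTR12 for H3K9me2 at percentile 2.905. On other settings single lists did: for H3K9me2, MLT1 was high with SD 1 (98.91) and with ranks (98.59) and MST low with the filter near 0 (0.385), and for H3K9me3, LTR7 was low with ranks (0.525) and MER high with the filter (97.73). The matched lists share the z-score level of the family, and with it much of the 5-aza-CdR value. A family's own difference can thus be matched away, so 0 of 9 does not show that no family differed.

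**Figure D3:**
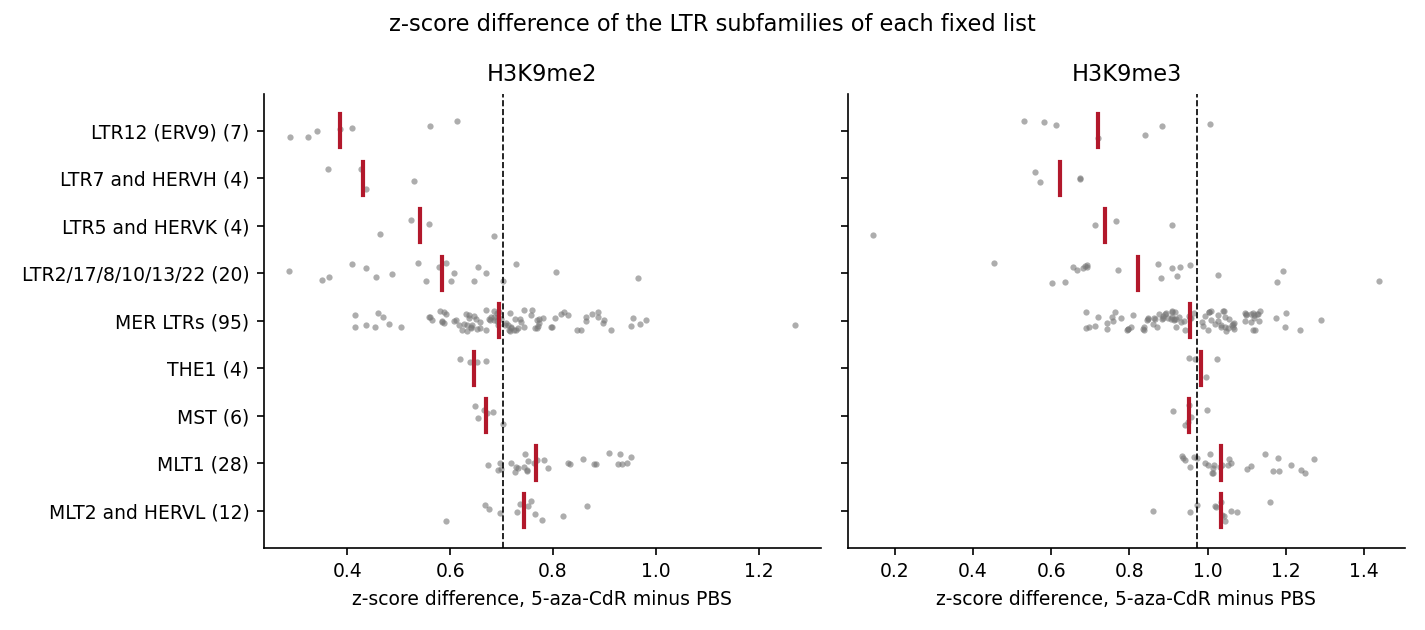
The z-score difference, 5-aza-CdR minus PBS (x axis), is shown for each LTR subfamily (grey points, jittered vertically) of the 9 lists with members (number in brackets), H3K9me2 on the left and H3K9me3 on the right. Red bars are list medians and the dashed line is the median of all 373 subfamilies (0.70 and 0.97), with LTR12 (0.39 and 0.72) and LTR7 (0.43 and 0.62) to its left.

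The last comparisons asked whether the 2 marks differed between treatments at the same LTRs, and whether the difference followed CpG density. Of the 11 subfamilies above the limit for H3K9me2 and the 7 for H3K9me3, 4 were shared (LTR10B1, LTR11, LTR86A1 and MER66D), where independent lists would share 0.206. Of the 30 and 27 below the limit, 18 were shared, where independent lists would share 2.17, or 5.82 if independent within each CpG group. The subfamilies behind these counts depend on the scale: with SD 1, 12 were shared above the limit and 4 below it (1.86 and 0.74 expected within CpG groups), with ranks 13 and 4 (2.1 and 0.93) and as residuals 14 and 2 (2.52 and 0.55), and of the 30 and 27 only 7 and 8 stayed below the limit with SD 1. Those 18, listed as a set after their values were seen, include LTR12B, LTR12C, LTR12E, LTR7, LTR7B, LTR7Y, LTR21A, LTR21B and HERV1_LTRb. Across subfamilies the differences of the marks had a Spearman correlation of 0.70 (0.63 to 0.76) and Pearson r of 0.74, and the partial Spearman correlation with CpG density held constant was 0.57. The expectations by independence do not allow for a z-score level that the marks share. As deposited, each difference followed its own 5-aza-CdR value (Spearman correlation 0.73 for H3K9me2 and 0.99 for H3K9me3). Those 5-aza-CdR values correlated at 0.85 between the marks. The marks have no library in common among those listed, and whether their z-scores share an input is not given in the sources used here.

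The difference was smaller at CpG-rich LTRs on the deposited scale. Its median was 0.58 in the high-CpG group, 0.71 in the intermediate group and 0.74 in the low-CpG group for H3K9me2, and 0.84, 0.99 and 1.05 for H3K9me3. The Spearman correlation with CpG density was -0.50 (-0.59 to -0.41) for H3K9me2 and -0.63 (-0.69 to -0.56) for H3K9me3, with Pearson r of -0.49 and -0.49. With SD 1 in each library the Spearman correlation was -0.08 (-0.19 to 0.04) for H3K9me2 and -0.13 (-0.24 to -0.03) for H3K9me3, and as residuals from the principal line it was 0.02 (-0.09 to 0.14) and 0.33 (0.23 to 0.42). For H3K9me2 both of these intervals include 0, so neither shows a direction. The H3K9me3 residual follows mainly the PBS z-score with its sign turned, so its positive value is not a reversed treatment difference. The strength of the relation between treatment difference and CpG density therefore depended on the scale.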

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

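The tests of explanations in this part were chosen after the results were seen. The scales they use (SD 1, ranks and residuals) had been fixed before, with an age foreseen where CpG density is used here. HERV-Fc2_LTR was picked out because its H3K9me2 z-score was lower in 5-aza-CdR than in PBS (difference -0.196) while its H3K9me3 z-score was higher (0.75). It was the only subfamily of 373 with opposite signs as deposited, but the sign depends on where each library is centred: with SD 1 and mean 0 both differences were below 0 (-2.64 and -0.61). Its H3K9me2 difference lay beyond the limit as deposited (-7.19 robust SDs from the median), with SD 1 (-6.11) and as a residual (-5.53). On ranks, where values at the ends can move little, it was within the limit (-0.854 robust SDs). Each mark has 1 library per treatment, and the difference between the marks was not tested.

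The z-score was higher in 5-aza-CdR at 372 (H3K9me2) and 373 (H3K9me3) of 373 LTR subfamilies. A candidate explanation is technical: a centre and scale of the z-scores set differently in each library, which would keep the order of the subfamilies. The order was kept in part, with a Spearman correlation between PBS and 5-aza-CdR of 0.87 for H3K9me2 and 0.603 for H3K9me3. A general difference in H3K9 methylation could keep the order as well, so the order cannot tell it apart from a difference of scale. Without replicates the noise in that order is also unknown. A biological candidate is a difference that follows the number of CpG sites at which 5-aza-CdR can act. That number is not given, and CpG density, whose denominator is not stated, stood in for it. Nearly all differences are above 0 on the deposited scale. There the Spearman correlation of the difference with CpG density was -0.50 (-0.59 to -0.41) for H3K9me2 and -0.63 (-0.69 to -0.56) for H3K9me3. The candidate would need a positive value, if density follows the number of sites. Over marks and scales only the H3K9me3 residuals had an interval above 0 (0.333), and these follow mainly the PBS z-score with its sign turned. A wider spread in 5-aza-CdR would by itself give a negative value on the deposited scale. With SD 1 in each library the correlation was -0.08 (-0.19 to 0.04) for H3K9me2 and -0.13 (-0.24 to -0.03) for H3K9me3. On ranks it was -0.0687 and -0.0249, with intervals that include 0. No positive relation with CpG density thus appeared on these scales either. The candidate stays open because the number of CpG sites itself was not tested.

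The smaller difference at CpG-rich LTRs may follow from the wider spread of the 5-aza-CdR z-scores, since CpG-rich LTRs have the lowest z-scores in each library. With equal SDs the Spearman correlation for H3K9me2 was -0.0773, with an interval that includes 0, against -0.50 before, as the wider spread predicts. For H3K9me3 it was -0.132 against -0.63 before, with an interval of -0.24 to -0.03. On ranks it was -0.0249 (-0.12 to 0.07), so whether any remainder exists beyond the spread stays open. The residuals (0.33, 0.23 to 0.42) cannot settle it, because for H3K9me3 they follow mainly the PBS z-score with its sign turned. A wider spread could itself be biological or come from the authors' scaling, and no value in the table separates the 2.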

How the results depend on the processing

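Leaving out single replicates was not possible with 1 library per group. No paired analysis was possible because each group holds 1 library. The alternatives that left subfamilies out by CpG density, round values or simple fractions were chosen after seeing the data, and the cause of the shifts was not tested except where the construction shows it. Subfamilies above and below the limit for H3K9me2 (11 and 30) became 30 and 11 with SD 1, 29 and 13 with ranks and 33 and 10 as residuals. They became 4 and 8 at 3 robust SDs and 4 and 10 at 2 ordinary SDs. The number above was 22 with the filter near 0 and 18 without the CpG-richest 10%. For H3K9me3 (7 and 27) the counts were 20 and 17 with SD 1, 2 and 7 at 3 robust SDs and 2 and 11 at 2 ordinary SDs. The H3K9me3 number above was 27 with ranks and 21 as residuals, and the number below was 1 with the filter, which left out 26 of the 27, and 15 without the CpG-richest 10%. Of the 30 H3K9me2 subfamilies below the limit, 7 were kept with SD 1, 3 with ranks and 5 as residuals. Of the 27 for H3K9me3, 8, 3 and 3 were kept.

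For H3K9me3 minus H3K9me2 in PBS (13 above, 4 below), ranks gave 22 and 10, a limit of 3 robust SDs gave 3 and 0, and the filter gave 0 below. The Spearman correlation between the marks in PBS (0.76) was 0.67 with the filter. The Spearman correlation between the marks' differences (0.70) was 0.57 with SD 1, 0.54 with ranks, 0.54 with the filter and 0.51 as residuals. The Spearman correlation of z-score with CpG density kept its sign in each library under each alternative. It moved beyond the interval to -0.68 for H3K9me2 PBS without the CpG-richest 10% and, with the filter, to -0.67 for H3K9me2 and -0.48 for H3K9me3 in 5-aza-CdR. The Spearman correlation of the H3K9me2 difference with CpG density (-0.50) was -0.0773 with SD 1, -0.0687 with ranks, 0.0249 as residuals and -0.37 with the filter. Those with SD 1, with ranks and as residuals had intervals that include 0. For H3K9me3 (-0.63) it was -0.13 with SD 1, -0.0249 with ranks and -0.44 with the filter. As residuals it was 0.33, on a scale that for H3K9me3 follows mainly the PBS z-score with its sign turned.

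The gap between low-CpG and high-CpG medians, in SDs over subfamilies, was 1.61 for H3K9me2 PBS, 1.67 for H3K9me2 5-aza-CdR, 1.17 for H3K9me3 PBS and 1.25 for H3K9me3 5-aza-CdR. With ranks these were 2.03, 2.06, 1.85 and 1.80. With 5 CpG groups they were 1.79 for H3K9me2 PBS, 1.97 for H3K9me2 5-aza-CdR and 1.77 for H3K9me3 5-aza-CdR. With the filter they were 0.92 for H3K9me2 5-aza-CdR, 1.43 for H3K9me3 PBS and 0.89 for H3K9me3 5-aza-CdR, and without the CpG-richest 10% 1.39 for H3K9me2 5-aza-CdR. The gap in the H3K9me2 difference (0.96) was 0.19 with SD 1, 0.0364 with ranks, 0.44 with the filter, 0.0126 as residuals and 1.56 with 5 groups. For H3K9me3 (1.11) it was 0.14 with SD 1, -0.0104 with ranks, 0.79 with the filter and 1.62 with 5 groups. As residuals, which for H3K9me3 follow mainly the PBS z-score with its sign turned, it was -0.50.

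Lists outside the central range (0 for each mark) numbered 1 for H3K9me2 with SD 1 (MLT1), with ranks (MLT1) and with the filter (MST), 1 for H3K9me3 with ranks (LTR7) and with the filter (MER; 0 of 4 LTR7 subfamilies were left), and 4 per mark against unmatched lists. Lists standing apart by level numbered 6 for H3K9me2 PBS, 5 for H3K9me2 5-aza-CdR, 4 for H3K9me3 PBS and 5 for H3K9me3 5-aza-CdR. Without LTR5 and LTR11 the LTR5 list no longer stood apart for H3K9me2 PBS (percentile 3.87, 5 lists left) and H3K9me3 5-aza-CdR (4.72, 4 left). Without the 4 simple-fraction subfamilies the MLT2 list no longer did for H3K9me2 PBS (97.49, 5 left), and the LTR5 list came to for H3K9me2 5-aza-CdR (2.44, 6 lists). Among named subfamilies, in robust SDs from the median, the H3K9me2 difference of HERV-Fc1_LTR1 came to lie just above the median (0.13 with ranks, 0.26 as residuals). The H3K9me3 residuals of LTR11 (-3.64), LTR81AB (-1.19), HERV-Fc1_LTR1 (1.63) and LTR22 (0.0057) lay on the other side from the deposited difference. Those residuals follow mainly the PBS z-score with its sign turned. H3K9me3 minus H3K9me2 of LTR11 reversed with SD 1 (5.10) and lay just above the median with ranks (0.0759). Over single subfamilies and lists, 288 further values kept their place, 50 came to lie within the limit and 13 came to lie outside the central range. A subfamily kept its place by staying beyond the limit, and a list by staying inside the central range. Subfamilies and lists left out by a setting were not counted. Depth could not be weighed, since no read counts come with these values.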

Other observations

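The groups and the test in this part were chosen after the data had been seen. Groups of subfamilies outside the fixed lists were formed by shared name, 10 had at least 4 members, and their percentiles are among random lists not matched on z-score. All values of these groups are on the deposited scale, on which the difference falls as CpG density rises. Only some of the percentiles looked at are named, and how many would stand apart by chance was not computed. Mammalian Gypsy-type LTRs (7 MamGypLTR subfamilies, median CpG density 0.00571) had median z-scores of -0.22 for H3K9me2 and -0.49 for H3K9me3 in PBS, at percentiles 99.17 and 96.82 of random lists, and 0.55 and 0.64 in 5-aza-CdR, at percentiles 99.31 and 98.63. The 5 LTR81 subfamilies had medians of -0.20 for H3K9me2 in PBS (percentile 99.15) and 0.66 for H3K9me3 in 5-aza-CdR (percentile 98.32), and did not stand apart for H3K9me3 in PBS (-0.49, percentile 94.53). The 12 LTR16 subfamilies stood apart for H3K9me2, with a median of -0.28 in PBS (percentile 98.88) and 0.49 in 5-aza-CdR (percentile 99.24), and did not for H3K9me3 in PBS (-0.50, percentile 75.34).

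At the other end, the 5 HERV1_LTR subfamilies had medians of -0.83 for H3K9me2 and -0.57 for H3K9me3 in PBS, both at percentile 0 of random lists. HERV1_LTRb departed from this group, with an H3K9me3 z-score of -0.36 in PBS exceeded only by those of LTR5 and LTR11. The 4 LTR3 subfamilies had an H3K9me2 median of -0.76 in PBS (percentile 0.09). On the deposited scale, their median difference of 0.70 for H3K9me2 was near that of all subfamilies. The LTR1 group (4 subfamilies, the name LTR1 with a letter or alone) had an H3K9me2 difference of 0.45, at percentile 0.29, without a low PBS level for that mark (-0.51, percentile 15.28). Its H3K9me3 difference of 0.73 was at percentile 0.96, with a PBS level of -0.54 at percentile 2.4. The 4 LTR14 subfamilies also had a low H3K9me2 difference (0.51, percentile 1.27) with a PBS level that did not stand apart (-0.59, percentile 4.04), and their H3K9me3 difference did not (0.81, percentile 5.08). Both LTR1 and LTR14 had low H3K9me2 levels in 5-aza-CdR (percentiles 1.57 and 1.41). Their median CpG densities of 0.0147 and 0.0145 lie in the range of the high-CpG group. As deposited, the H3K9me3 difference also stood apart for HERV1_LTR (percentile 1.12), LTR81 (98.51) and MamGypLTR (98.34), and other scales were not tried for these groups. The 5 LTR86 subfamilies had an H3K9me2 difference of 0.86, at percentile 98.64, and an H3K9me3 difference of 1.004, at percentile 63.3, which did not stand apart.

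The z-scores of LTR11 and LTR5 for H3K9me3 hold the only round numbers among the z-scores: 3 of 1492 z-scores have 3 or fewer decimals (-0.3 for LTR5 and LTR11 in PBS and 2 for LTR11 in 5-aza-CdR), and the others have at least 14. Both -0.3 values are the highest of their library, where the highest of the other subfamilies is -0.36. The value of 2 is also the highest of its library, where the next is 0.94. How these 3 values arose is not given in the sources used here.

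One hypothesis was that the most extreme subfamilies rest on few genomic copies. The CpG densities of 4 subfamilies equal a fraction with a denominator of at most 1000000 within a relative error of 1e-15, while the nearest of the other 369 misses by 2.1e-12: HERV-Fc1_LTR2 is 29/432, LTR11 is 1/585, HERV-Fc1_LTR3 is 2251/47600 and HERV-Fc2_LTR is 3451/104340. An average over many copies would rarely give such a fraction, so these values may come from 1 or a few sequences each. If few copies made the z-scores noisy, these 4 subfamilies should lie far from the trend of z-score on CpG density. Their mean absolute residual over the 4 libraries was 1.997, 4.09, 0.97 and 1.63 residual SDs in the order above, and the median of 1.81 was at percentile 99.96 of 10000 random sets of 4, against a median of 0.60 over all subfamilies. This decides nothing, because the z-scores of these 4 had been seen when the test was chosen, and because they rank 1, 373, 4 and 6 by CpG density, at the ends of the range, where a straight trend may fit poorly and with which the random sets were not matched. Whether few copies lie behind their z-scores stays open. Leaving them out moved the Spearman correlation of z-score with CpG density in PBS only from -0.74 to -0.73 for H3K9me2 and from -0.61 to -0.60 for H3K9me3.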
